A study of Homo sapiens with 6 samples.

How the data were processed

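Gene expression was measured in 6 samples of MDA-MB-231 cells, 3 at 0 h and 3 after 12 h of dinaciclib, on an oligonucleotide array with 22277 probe sets and a single biotin label. Per the labels' protocols, the drug was dissolved in DMSO and added to the growth medium, and total RNA was extracted with Trizol. The deposited values are linear intensities, 1 per probe set and array, which the values themselves show, since they were not on a log scale and not brought to a common median. The method that turned the probes' brightness into these values is not given in the sources used here, so its background correction and scaling stay unknown. All 6 columns of the table were used.

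Probe sets were named from the platform's annotation, with symbols looked up by gene identifier in a RefSeq gene table of the assembly GRCh38.p14, used only for names. With the controls left in, 19070 probe sets had 1 gene symbol, of which 19058 matched by gene identifier, and 0 symbols needed an update. After 62 control probe sets were left out, 19064 probe sets had 1 gene, 1043 had several and 2108 had none named. Each gene was represented by its probe set with the highest mean over all 6 samples, which gave 11963 genes. A further 3151 probe sets without a single gene were tested and entered the adjustment, but were not named and not counted as genes. Of the genes, 4310 had 2 or more probe sets.

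Values were tested as log2(value + 1) without further normalization, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and the group as the only term, and p-values of the 15114 rows were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale and understate changes of dim genes. Gene lists were tested with camera, with a preset inter-gene correlation of 0.01, for the 27 lists with at least 5 measured members, of 31 fixed. No mitochondrially encoded transcript had a named probe set, and 2 lists by gene span were not run, because no genome build is named for the files. The result of 1 further list is not reported here. The test, the lists and most alternatives were fixed before the data were examined.

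Named genes followed a rule fixed at the same time. It took the 10 highest and 10 lowest log2 changes among genes past the threshold whose groups did not overlap, in each list the members past the threshold with the 2 largest rises and 2 largest falls, and a fixed set of genes of DNA repair, transcriptional kinases, survival, proliferation and housekeeping.

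Alternatives were quantile normalization, centring on the array median or on spiked control probe sets, a replicate block, a batch covariate for letter against number in the titles, no dim genes (under the 40th percentile), a variance trend with robust estimation, the mean of a gene's probe sets, every probe set, log2(value + 16), each sample left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were the numbered samples alone, the hybridization or labelling controls alone, an estimated correlation on quantile-normalized values, scanned gene groups without members of fixed lists, and each list beside 10000 random lists in which every member was drawn from the 200 genes nearest to it in mean signal. No pair of samples held identical values (0%), and log2 values correlated at 0.963 to 0.972 within and 0.937 to 0.947 between groups.

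The steps were tested on simulated data drawn from the means and spreads of the 15114 rows. With 200 changed rows, 0% were recovered at a simulated log2 change of 1, 58.1% at 2 and 77.9% at 3. With 2267 changed rows, 36.1% were recovered at 1 and 81.8% at 2, with 5.64% and 5.17% of calls false. Of 200 unchanged lists, 3.5% fell under a p of 0.05 in camera, in data simulated with independent genes. For genes with probe sets called in opposite directions, 59.3% of 253 simulated genes among 4310 were recovered and 2.60% of calls were false. With a simulated trend of change with brightness, 4% of 100 unshifted lists lay outside the range of random lists of like brightness. A test of differential use of probe sets (diffSplice) made 17.9% false calls among the same 4310 genes in simulation and was not used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.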

Results

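Messenger RNA was measured with oligonucleotide arrays in MDA-MB-231, a triple-negative breast cancer cell line, before and after treatment with dinaciclib, a small molecule that inhibits several cyclin-dependent kinases, among them CDK1, CDK2, CDK5 and CDK9. The group called baseline held 3 samples taken at 0 h, with the replicate names E, 4 and 5, and the group called dinaciclib held 3 samples taken 12 h after the drug, with the names F, 4 and 5. The labels give no dose and do not say whether baseline cells received the solvent, and no source used here says that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each array gave 1 intensity per probe set, with median intensities of 53.3, 66.2 and 60.8 in baseline E, 4 and 5 and of 43.3, 46.8 and 40.6 in dinaciclib F, 4 and 5. The number of arrays limits the precision of every value.

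The comparison asked which transcripts differed after 12 h of dinaciclib. No sample was kept for 12 h without the drug. Effects of the drug therefore cannot be told apart from those of time in culture, handling or solvent. Many transcripts of DNA repair and mitosis genes fell, several short-lived transcription factor transcripts rose, and none of the measured cytosolic ribosomal protein transcripts passed the test. BRCA1, which acts in homologous recombination, fell from 8.31 ± 0.12 to 5.86 ± 0.47 log2 units (SD, n = 3 per group), a log2 change of -2.45 with a standard error of 0.27 (limma, Benjamini-Hochberg adjusted p = 0.00455). JUNB, an AP-1 transcription factor, rose from 6.46 ± 0.10 to 8.98 ± 0.37 log2 units (SD, n = 3), a log2 change of 2.51 with a standard error of 0.24 (limma, Benjamini-Hochberg adjusted p = 0.00353). Of 11963 genes, 2388 changed, of which 423 rose and 1965 fell, and 308 rose and 1596 fell at least 2-fold. Fewer passed with 5 samples, 1153 without baseline 4, 1118 without baseline 5, 1448 without dinaciclib 4 and 1396 without dinaciclib 5. In 4791 genes, 40.05% of those tested, the values of the groups did not overlap. Chance gives 10%, but only if the arrays do not differ as a whole. The median intensities of the groups did not overlap either, so part of the excess can come from scaling.

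The balance of rises and falls depended on how the arrays were scaled. As deposited, the median gene had a log2 change of -0.26 and 82.3% of the called genes fell. Quantile normalization moved that median to -0.02 and gave 1064 raised and 1606 lowered genes. Centring each array on its median moved it to 0.19 and turned the balance, with 1950 raised and 1300 lowered genes. Centring on all spiked control probe sets moved it to -0.37, with 200 raised and 1558 lowered genes, and so did the hybridization controls alone, at -0.36 with 515 raised and 2843 lowered, and the labelling controls alone, at -0.38 with 95 raised and 1054 lowered. Medians of called gene lists are therefore also given below relative to the median gene. The change also varied with brightness, so called lists were also set beside random lists of genes of like mean signal, a comparison chosen after seeing the data.

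**Figure D1:**
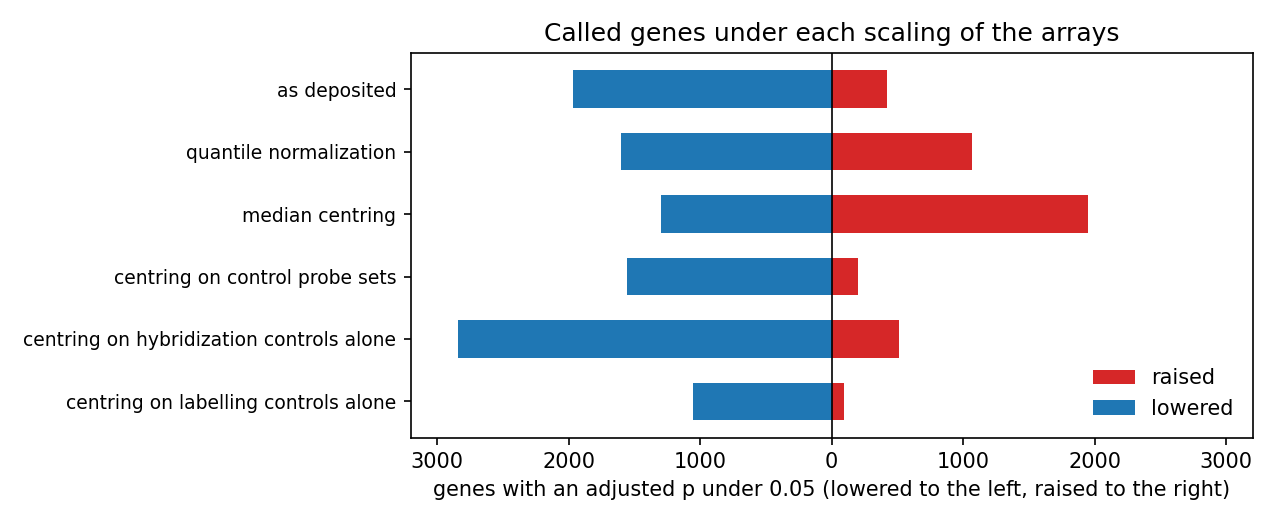
Bars give the number of genes past an adjusted p of 0.05 that were raised (right, red) or lowered (left, blue) under each scaling of the 6 arrays. Lowered genes outnumber raised ones in 5 of the 6 rows, and median centring shows 1950 raised against 1300 lowered genes.

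Samples named with a letter stood apart in both groups. The 18S ribosomal RNA control (5-prime probe set) read 736 in baseline E against 8273 and 8642 in baseline 4 and 5, and 1155 in dinaciclib F against 8688 and 9061 in dinaciclib 4 and 5. With letter or number as a batch covariate, 2885 genes changed, of which 599 rose and 2286 fell. Within the 4 numbered samples, 1409 genes changed, of which 230 rose and 1179 fell, and 1265 of them were also called from all 6 samples. The letter batch holds 1 sample per group and gives no test. Of the 1409 genes called from the numbered samples, 1345 (95.5%) moved the same way from E to F, samples that had no part in calling them. Most of the 1409 were falls, and F was dimmer than E (median intensity 43.3 against 53.3). Some agreement would therefore arise without any change of single genes, and the share over all genes was not analysed here.

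The largest falls past the threshold with no overlap of groups were those of NLRP1 (log2 change -4.89, standard error 0.28), an inflammasome sensor, KRCC1 (-4.25, 0.20), ARHGAP22 (-4.11, 0.25), SMARCAL1 (-4.10, 0.71), an annealing helicase at stalled replication forks, and JMJD4 (-4.10, 0.29). ZBTB48, DOCK10, SLC24A1, SNCAIP and CCRL2 followed, with log2 changes between -3.91 and -3.71. The largest rises were those of CCDC88C (4.04, 0.21), KLF13 (3.68, 0.31), a Krüppel-like transcription factor, ARC (3.63, 0.69), an immediate early gene of neurons, STAMBPL1 (3.44, 0.59) and SYBU (3.19, 0.24). SLC39A9, CSNK1E, ABL2, GTF3C4 and CNTF followed, with log2 changes between 3.14 and 3.01. Mean intensities lay under 16 after dinaciclib for NLRP1, SMARCAL1, JMJD4, ZBTB48, DOCK10, SLC24A1 and SNCAIP, and at baseline for KLF13, ARC, STAMBPL1, CSNK1E and CNTF, so the sizes and ranks of these changes depend on the value added before the logarithm. With log2(value + 16) each of them still passed, but the change was -2.52 for NLRP1, 1.95 for KLF13, 2.05 for ARC and 1.13 for CNTF. SLC39A9 rose on 1 of its 3 probe sets. DOCK10 fell on 1 of its 2 probe sets and SLC24A1 on 1 of its 4.

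Of 24 measured homologous recombination genes, 14 fell, 0 rose and 10 did not pass the test, and adjusted over the list alone 17 fell. The median log2 change was -1.04, or -0.78 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 5.89e-06 with a preset correlation; adjusted p = 0.911 with an estimated correlation). The middle 95% of the medians of random lists of like brightness ranged from -0.72 to -0.04. DNA2, a nuclease and helicase of end resection, had a log2 change of -2.90 with a standard error of 0.20, BRIP1, a helicase that binds BRCA1, one of -2.71 with a standard error of 0.22, and BRCA1 fell on both of its probe sets. BRCA1, BRIP1 and DNA2 passed whichever 1 sample was left out. At the preset correlation 9 lists were called in all, and another split of the 6 samples that mixed the groups called 8. BRCA2 and FANCD2 were not analysed here.

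Damage signalling and checkpoint genes fell in 12 of 20 measured members, with 0 rises, 8 not past the test and 13 falls adjusted over the list alone. Their median log2 change was -1.03, or -0.78 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.00075; adjusted p = 0.911 with an estimated correlation). CDC25C, the phosphatase that activates CDK1, fell by 2.71 on the log2 scale (standard error 0.23) and MDC1, a scaffold at damaged chromatin, by 2.15 (standard error 0.25). The damage kinases ATR and ATM fell by 1.96 (standard error 0.21) and 1.41 (standard error 0.21) on their brightest probe sets, and their other probe sets fell too.

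Of 14 Fanconi anaemia and crosslink repair genes, 5 fell, 0 rose and 9 did not pass the test, and adjusted over the list alone 8 fell. The median log2 change was -0.77, or -0.51 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.00448; adjusted p = 0.911 with an estimated correlation). That median lay within the range of random lists of like brightness (-0.99 to -0.06). FANCE fell by 1.82 (standard error 0.25), FAN1, a crosslink repair nuclease, by 1.69 (standard error 0.18) and FANCI by 1.11 (standard error 0.18) on the log2 scale, of which FANCI did not pass without baseline 5. Of 24 excision and mismatch repair genes, 7 fell, 1 rose and 16 did not pass, with 11 falls and 1 rise adjusted over the list alone and a median of -0.64, or -0.38 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.0196; adjusted p = 0.911 with an estimated correlation). MUTYH (-1.92, standard error 0.37) and PMS1 (-1.88, standard error 0.18) fell and XPA (1.16, standard error 0.23) rose. This call ended without dim genes (adjusted p = 0.118), with labelling controls alone (0.0677) and under median centring (0.0509), and the median lay within the range of random lists of like brightness (-0.72 to -0.02). Non-homologous end joining genes had 2 falls, XRCC4 (-1.42) and POLL, whose mean intensities lay under 16 in both groups, among 8 members, 0 rises, the same 2 falls adjusted over the list alone, and no call (camera, Benjamini-Hochberg adjusted p = 0.416).

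Of 34 G2/M and mitosis genes, 19 fell, 0 rose and 15 did not pass the test, with 22 falls adjusted over the list alone. The median log2 change was -0.88, or -0.62 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.000378; adjusted p = 0.911 with an estimated correlation). ESPL1, the protease separase, fell by 2.86 (standard error 0.31), AURKB, a mitotic kinase, by 2.47 (standard error 0.22) and TOP2A, topoisomerase II alpha, by 1.42 (standard error 0.18). MKI67, a proliferation marker, did not pass on its brightest probe set (0.30, standard error 0.24), while 2 of its 4 probe sets fell, with log2 changes of -2.09 and -2.19. Of 34 G1/S and DNA replication genes, 10 fell, 1 rose and 23 did not pass, with 11 falls and 1 rise adjusted over the list alone. The list was not called as deposited (camera, Benjamini-Hochberg adjusted p = 0.0861) but was under other settings, among them quantile normalization (0.0325), the batch covariate (0.0394), the numbered samples alone (0.0239) and without baseline E (0.0147). The replication factors POLA2 (-2.73, standard error 0.48) and GINS1 (-2.69, standard error 0.27) fell and GINS3 (1.07, standard error 0.25) rose.

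Among transcripts of the kinases themselves, CDK12 fell by 2.11 (standard error 0.31), CDK9, the kinase of the elongation factor P-TEFb, by 1.39 (standard error 0.27) and CDK2 by 0.88 (standard error 0.21) on the log2 scale. CDK9 did not pass within the numbered samples or without baseline 4 or 5, and CDK2 passed in none of the fits that left out baseline 4 or 5 or a dinaciclib sample. CDK1 (0.30, standard error 0.22) and CDK5 (-0.12, standard error 0.24) did not pass, though CDK1 rose under median centring (0.75), and CDK5 changed sign between scalings. MEPCE, which caps the 7SK RNA that holds P-TEFb inactive, fell (-1.46, standard error 0.29), while AFF4 (1.84, standard error 0.34), a scaffold of the super elongation complex, and CCNT2 (1.67, standard error 0.18), a cyclin partner of CDK9, rose. In the whole list of CDKs, cyclins and P-TEFb, 4 of 31 members rose, 7 fell and 20 did not pass, with 4 rises and 8 falls adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.572). CCNK (0.43, standard error 1.17), HEXIM1 (-0.92, standard error 0.27) and POLR2A (-0.69, standard error 0.32) did not pass.

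**Figure D2:**
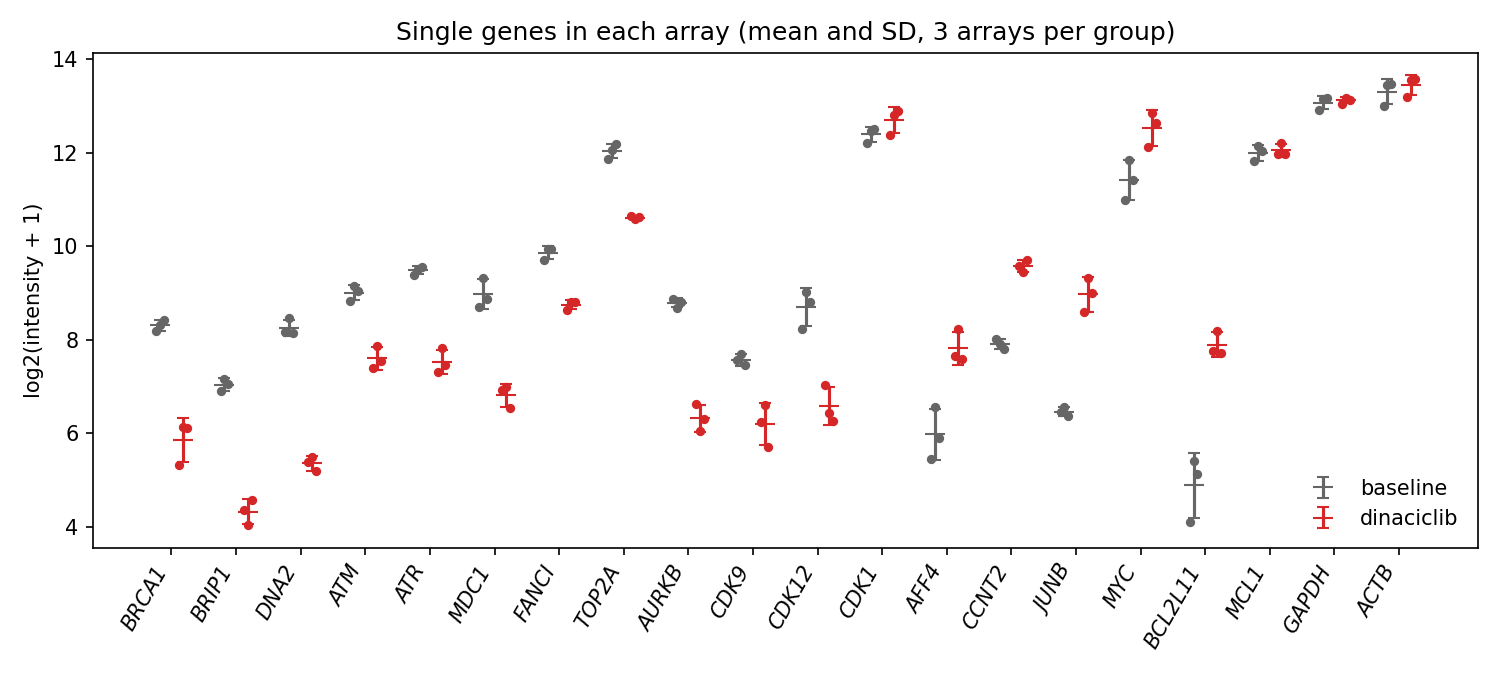
Points are single arrays, bars the mean and SD of 3 arrays, in log2(intensity + 1) on the vertical axis, for baseline (grey) and dinaciclib (red) samples, each gene on its brightest probe set. BRCA1 lies near 8.31 at baseline and 5.86 after dinaciclib, while the groups of MCL1, GAPDH and ACTB lie on top of each other as deposited, though MCL1 and GAPDH were called as raised under median centring.

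Of 40 immediate early and short-lived factor genes, 11 rose, 3 fell and 26 did not pass, with 14 rises and 4 falls adjusted over the list alone. The median log2 change was 0.43, or 0.69 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 1.16e-06; adjusted p = 0.911 with an estimated correlation). JUNB and FOSL2 (1.89, standard error 0.26) rose, and JUND (-1.39, standard error 0.31) and KLF2 (-0.94, standard error 0.20) fell, though KLF2 no longer passed after quantile normalization or median centring. MYC had a log2 change of 1.12 with a standard error of 0.31 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0518), but passed with the batch covariate (0.0171).

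Apoptosis genes moved both ways. BCL2L11, which encodes the pro-apoptotic protein BIM, rose by a log2 change of 3.01 (standard error 0.38) on its brightest probe set, and its other probe set, dim at baseline (3.67 log2 units), rose too, while APAF1 (-1.65, standard error 0.24, on 1 of its 3 probe sets) and DIABLO (-0.99, standard error 0.19) fell. Of 16 pro-apoptotic genes, 1 rose, 5 fell and 10 did not pass, with 3 rises and 5 falls adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.889). Of 10 anti-apoptotic genes, BCL2L2 (-1.77, standard error 0.21) and BCL2 (-1.21, standard error 0.26) fell, 0 rose and 8 did not pass, with 2 rises and 3 falls adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.889). MCL1, a short-lived survival protein, did not pass on its brightest probe set (0.06, standard error 0.19), while 2 of its 5 probe sets fell, with log2 changes of -1.06 and -0.89. XIAP (0.62, standard error 0.20) did not pass as deposited and passed after quantile normalization (1.10). Its other probe set went the other way as deposited (-0.43, standard error 0.25) and did not pass.

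Of other named genes, ZMAT3 (1.61, standard error 0.21) and GADD45B (1.34, standard error 0.28) rose and TNFRSF10B, a death receptor, fell (-2.23, standard error 0.21) on 1 of its 3 probe sets. MDM2 fell on its brightest probe set (-1.64, standard error 0.30), and the mean of its probe sets turned the sign (0.97). Another of its probe sets passed as raised, with mean intensities of 0.942 at baseline and 18.2 after dinaciclib, near the floor. Its remaining probe sets, with baseline mean intensities of 8.92, 16.6 and 12.1, had log2 changes of 0.94, 0.93 and 1.33. They did not pass as deposited, but with log2(value + 16) the last of them did (0.71, limma, Benjamini-Hochberg adjusted p = 0.0338). CDKN1A (-0.69, standard error 0.21) and CCND1 (-0.46, standard error 0.26) did not pass.

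None of 52 cytosolic ribosomal protein genes and none of 61 nuclear oxidative phosphorylation genes passed, also adjusted over the list alone, and their medians were 0.09 and 0.11, or 0.35 and 0.37 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.000605 and 0.00075; adjusted p = 0.911 for both with an estimated correlation). Both calls ended after quantile normalization (adjusted p = 0.581 and 0.339), that of oxidative phosphorylation also without baseline E (0.0654), and centring on the control probe sets took the ribosomal median below 0 (-0.03). Both lists are bright, and random lists of like brightness had medians of 0.10 and 0.07, with ranges of 0.05 to 0.16 and -0.02 to 0.17 that held both lists, though the genes drawn for the ribosomal list were dimmer than it (median 12.6 against 13.2 log2 units). Of 19 genes of the histone list, H2BC21 (1.25, standard error 0.20) and H3C2 (0.82, standard error 0.19) rose, 0 fell and 17 did not pass, with 2 rises adjusted over the list alone and a median of 0.18, or 0.44 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.0126; adjusted p = 0.911 with an estimated correlation). The histone call ended without baseline E (0.0959). H2AX, a variant histone kept in the damage signalling list, fell (-1.28, standard error 0.24). As deposited, GAPDH (0.05, standard error 0.18) and ACTB (0.13, standard error 0.23) did not pass, and median centring called GAPDH as raised (0.50).

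The other lists were not called as deposited, though glycolysis (0.0299) and splicing factors (0.00482) were under median centring and interferon response (0.049) with every probe set (camera, Benjamini-Hochberg adjusted p). Among 29 interferon response genes 7 fell, 0 rose and 22 did not pass, with 9 falls adjusted over the list alone, led by XAF1 (-2.39, or -1.61 with log2(value + 16), as it was dim after dinaciclib) and RIGI (-1.78), a sensor of viral RNA (camera, Benjamini-Hochberg adjusted p = 0.135). The median of the interferon list, -0.45, lay within the range of random lists of like brightness (-0.72 to -0.06). Among 27 NF-kB, cytokine and chemokine genes 3 rose and 2 fell, with 4 and 3 adjusted over the list alone, among them PTGS2 (1.97), NFKB1 (1.59), IL11 (-1.75) and NFKBIE (-1.33). Of 27 unfolded protein and integrated stress response genes 1 rose (CEBPG, 0.92) and 5 fell, also adjusted over the list alone, among them CHAC1 (-2.50, or -1.47 with log2(value + 16), as it was dim after dinaciclib) and DDIT3 (-2.25). HSPH1 (0.64) rose alone among 12 heat shock genes and did not pass adjusted over the list alone. Splicing factors had 2 rises (CLK1, 1.35, and RBM39, 0.76) and 3 falls (among them SF3B3, -1.26, and U2AF1, -0.94) in 33 members, with 0 rises and 2 falls adjusted over the list alone. The rises of CEBPG, HSPH1 and RBM39 just missed the threshold when every probe set was tested (limma, Benjamini-Hochberg adjusted p = 0.0507, 0.0527 and 0.0518). None of 22 glycolysis genes passed, and 1 of 18 sterol synthesis genes fell (SREBF1, -1.45), with 0 adjusted over the list alone. Of the zinc finger genes named ZNF, 26 rose, 54 fell and 151 did not pass, with 31 and 64 adjusted over the list alone, led by ZNF112 (1.93), ZNF26 (1.60), ZNF764 (-3.00) and ZNF76 (-2.88). With log2(value + 16) the falls of ZNF764, dim after dinaciclib, and ZNF76 were -1.98 and -2.25, so their order depended on the added value. Of 32 mesenchymal and basal breast cancer genes 4 fell, also adjusted over the list alone, among them EGFR (-2.41, with 2 of its 6 probe sets lowered) and MET (-1.56, with 1 of 4). These 9 lists had camera adjusted p-values between 0.135 and 0.945 (Benjamini-Hochberg).

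Markers of other cells gave no call. Of 20 luminal breast epithelium markers 4 fell, among them SPDEF (-2.72) and MLPH (-2.52), 1 of 13 leukocyte markers fell (CD14, with mean intensities of 24.7 at baseline and 2.07 after dinaciclib, and a change of -1.15 with log2(value + 16)), and none of 11 fibroblast markers and none of 4 erythrocyte and serum markers passed, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.527 for the luminal, leukocyte and fibroblast lists, with the erythrocyte list too small to test).

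**Figure D3:**
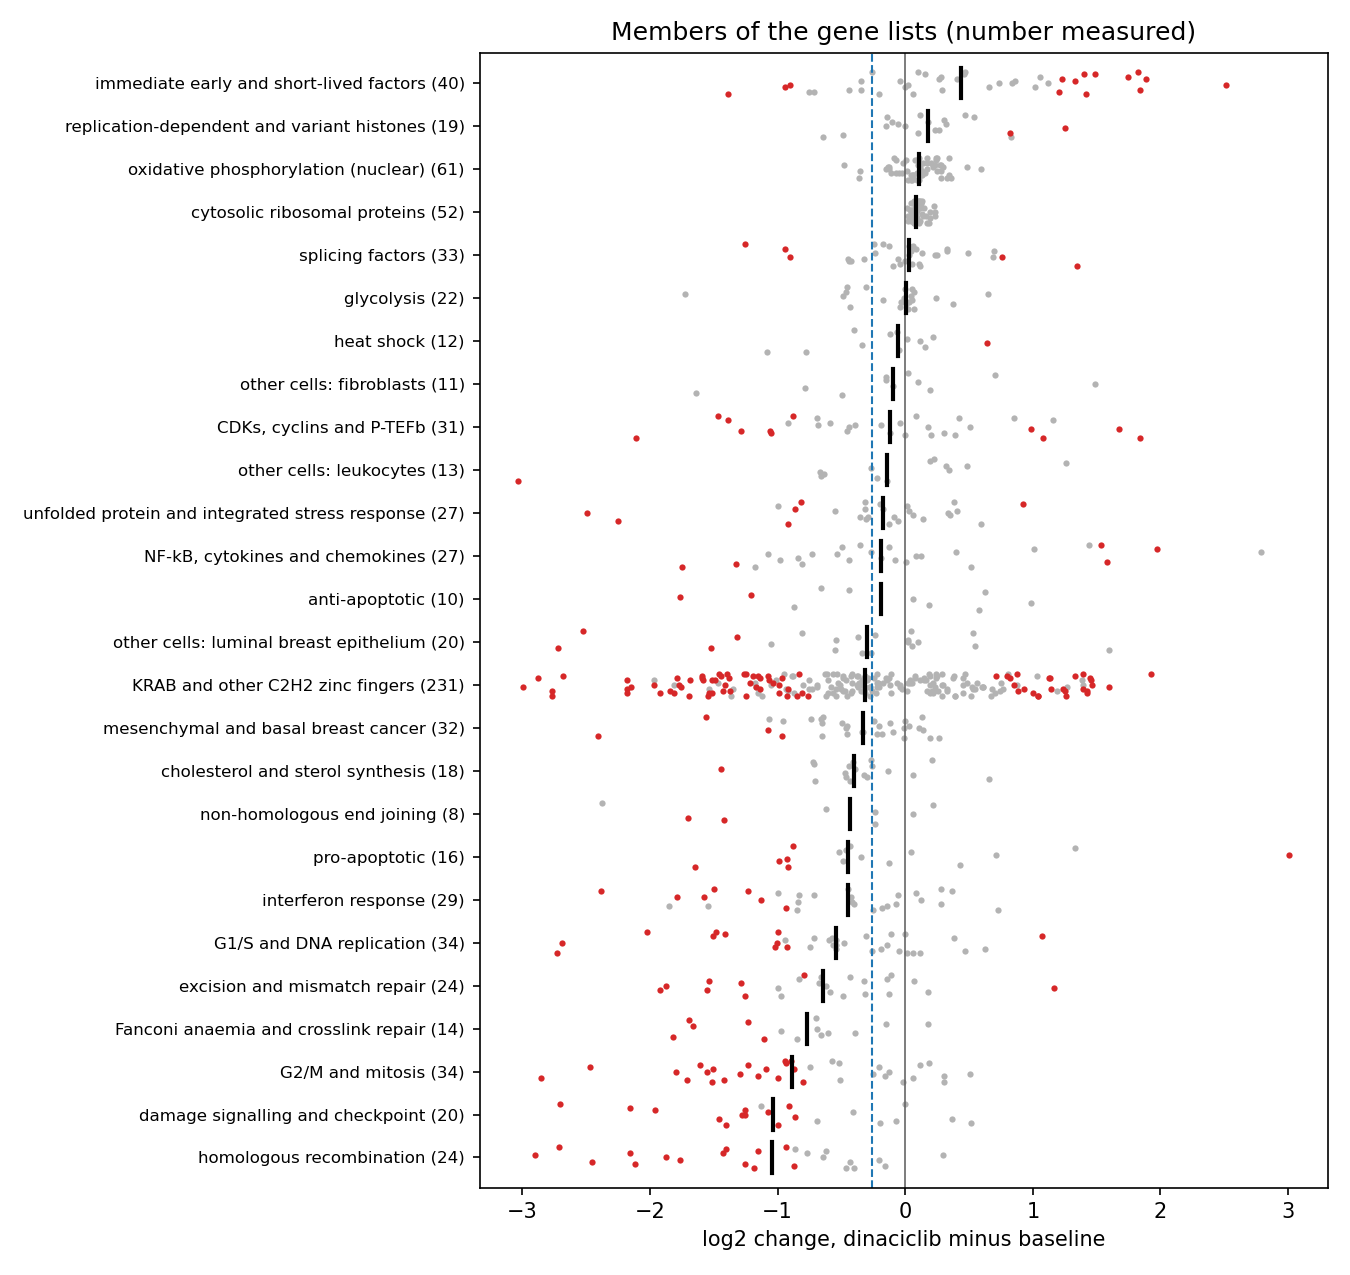
Each point is 1 gene, placed by its log2 change (dinaciclib minus baseline), red where it passed an adjusted p of 0.05 and grey where it did not, with the list's median as a black bar and the number of measured members in brackets. The dashed line marks the median gene at -0.26, and the median of homologous recombination lies lowest at -1.04, that of immediate early factors highest at 0.43.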

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

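Of 20 control probe sets for human and other transcripts that the comparison left out, 1 had all 3 dinaciclib samples above all 3 baseline samples and a difference of at least 2-fold. This was the 3-prime probe set of 28S ribosomal RNA, with a mean of 3.60 ± 0.75 at baseline and 5.69 ± 0.45 after dinaciclib (log2, SD, n = 3), a difference of 2.10. Its baseline intensities of 15.8, 5.62 and 14.9 lay under 16, near the floor, so the size of the difference depends on the value added before the logarithm. The 5-prime and middle probe sets of the same RNA differed by 0.10 and 0.22. Groups of 3 samples were not tested for outliers.

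The tests in this paragraph were chosen after the excess of falls was seen, except the splits. Of 2388 called genes, 1965 fell and 423 rose. The hybridization controls differed by 0.10 with a standard error of 0.09, above the shift of the median gene of -0.26. This argues against weaker hybridization or scanning that dims all probe sets of the dinaciclib arrays alike. These controls were bright on average (10.5 and 10.6 log2 units), where genes also moved little. Among 10 groups ordered by mean signal, the median change was -0.12 in the ninth and 0.09 in the brightest, against -0.59 in the sixth. A dimming that varies with brightness stays open. RNA degradation stays open, since log2 ratios of 3-prime to 5-prime signal differed by -0.17 for ACTB (standard error 0.32) and -0.0515 for GAPDH (standard error 0.03). The ACTB ratio itself was high in both groups, 2.52 at baseline and 2.35 after dinaciclib (log2). It was lower in E and F (2.09 and 1.86) than in the numbered samples. Scaling stays open too, since median centring left 40% and quantile normalization 60.2% of calls as falls, and centring itself sets this outcome. An effect of the drug on most transcripts is untested. The 6 samples allow 10 splits of 3 against 3, too few for a share under 0.05: the real split (1 of 10) gave 2388 changed, 423 raised, 1965 lowered, 308 and 1596 at least 2-fold, and the highest other gave 0 of each.

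In 40 genes, probe sets of the same gene were called in opposite directions. KLHL20 had log2 changes of -2.32 and 4.29, SENP6 of -1.45 and 4.31 and NFIB of -1.26 and 4.17, genes chosen after their values were seen. The number depended on scaling: it was 74 after quantile normalization, 70 after median centring, 69 with hybridization controls, 21 with all spiked controls and 13 with labelling controls, where all calls fell to 1149 genes, and of the 40 genes 29, 27, 38, 21 and 13 were among them. The median difference between the probe sets was 3.38 as deposited and 3.37 after quantile normalization, a comparison added after that result. A scaling of whole arrays largely cancels in a difference between 2 probe sets on the same arrays. The genes were also chosen for opposite calls, so this comparison could hardly come out otherwise and decides nothing about scaling. Probe sets whose suffix marks shared sequence were less frequent among these genes (odds ratio 0.529, Fisher's exact two-sided p = 0.00238). This argues against shared sequence as far as the suffix shows it. Without dim probe sets 31 of the 40 genes remained among 71, which argues against probe sets near the floor in both groups. That filter used the mean over all 6 samples, so a probe set near the floor in 1 group can pass it. Signal near the floor in 1 group therefore stays open. A candidate explanation that stays untested is a change in transcript form, such as use of earlier ends, since probe positions were not analysed here. The real split gave 40 such genes and the highest of the other splits 0, with 10 splits too few for a share under 0.05.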

How the results depend on the processing

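No paired design was assumed: replicate numbers 4 and 5 occur in both groups, and deviations from the group means correlated at 0.0889 for number 4, 0.0815 for number 5 and 0.143 for E with F, against at most 0.0228 for other pairs across groups, a hint from the data and not the design. With numbers 4 and 5 as a replicate block, limma called 0 genes in every count, with 4093 at an unadjusted p under 0.05 (4069 without the block), and G1/S and DNA replication was called (adjusted p = 0.0437). In that fit E and F each had a term of their own, so the change rested on the numbered samples alone. Few residual degrees of freedom were left, so the 0 calls cannot tell lost power from an effect of pairing. With E and F as a further pair in the replicate block, 2305 genes were called, of which 1983 were also called without a block.

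Quantile normalization gave 1064 raised genes, with 526 raised and 919 lowered at least 2-fold, and adjusted p-values of 0.0325 for G1/S, 0.581 for ribosomal proteins and 0.339 for oxidative phosphorylation. Median centring gave 1950 raised and 1300 lowered genes, 803 and 799 at least 2-fold, and adjusted p-values of 0.0509 for excision repair, 0.0299 for glycolysis and 0.00482 for splicing factors. Centring on all control probe sets gave 200 raised genes, also at least 2-fold. Labelling controls alone gave 1149 changed, 95 raised and 1054 lowered genes, the same at least 2-fold, and 0.0677 for excision repair. Hybridization controls alone gave 0.0431 for G1/S. Raised genes numbered 674 without dim genes (0.118 for excision repair), 675 with trend and robust estimation and 645 with log2(value + 16) (0.0449 for G1/S). Testing every probe set gave 473 genes raised at least 2-fold, 0.0455 for G1/S and 0.049 for interferon response. The batch covariate gave 0.0394 for G1/S, and the numbered samples alone 1409 changed, 230 raised and 1179 lowered genes and 0.0239 for G1/S. The cause was not tested.

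With an estimated correlation camera called 0 lists, each of the 9 lists called before having an adjusted p of 0.911, and 0 on quantile-normalized values: 0.219 for homologous recombination and damage signalling, 0.582 for Fanconi genes, 0.44 for excision repair and immediate early factors, 0.544 for G2/M, 0.647 for histones, 0.671 for ribosomal proteins and 0.809 for oxidative phosphorylation. Directional fry gave 0.0705 for immediate early factors, 0.386 for histones, 0.583 for ribosomal proteins, 0.689 for oxidative phosphorylation and 0.036 for interferon response. Mixed fry, which asks for change in either direction, called 23 lists, with 0.452 for ribosomal proteins and 0.37 for oxidative phosphorylation, and, among those newly called, 0.00101 for end joining, 0.00026 for G1/S, 6.14e-05 for CDKs, 1.57e-05 for splicing factors, 0.000156 for anti-apoptotic, 0.000138 for pro-apoptotic, 0.000902 for NF-kB, stress response and mesenchymal genes, 0.022 for heat shock, 0.000312 for interferon response, 0.0295 for glycolysis, 3.71e-05 for zinc fingers, 0.000115 for luminal and 0.00149 for leukocyte markers. Fry asks whether a list's own genes changed, not whether they changed more than other genes. With 2388 of 11963 genes called, mixed fry can call most lists, so these calls single out none. The leukocyte list, for example, had 1 of 13 members past the threshold. The real split called 9 lists with the preset correlation and another split, which set E, F and baseline 5 against the other samples and so mixed the groups, called 8, and 10 splits are too few for a share under 0.05.

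Leaving out 1 sample at a time gave 1118 to 2154 changed, 185 to 316 raised and 898 to 1838 lowered genes, 184 to 295 raised and 895 to 1608 lowered at least 2-fold, and 8 to 9 lists. The counts of changed genes moved by over 1.5 times without baseline 4 (1153) or 5 (1118) and without dinaciclib 4 (1448) or 5 (1396). Adjusted p-values ranged from 0.0147 to 0.26 for G1/S, 7.13e-05 to 0.0654 for oxidative phosphorylation and 0.00472 to 0.0959 for histones, with the call of G1/S gained and those of the other lists lost without baseline E. Of 86 named genes past the threshold, 59 also passed whichever 1 sample was left out, 27 missed it without at least 1 sample and 0 changed sign. A group mean intensity under 16 was seen in 17 of the 86, and all 17 also passed with log2(value + 16). MDM2 turned from -1.64 to 0.97 with the mean of its probe sets and to 3.30 with every probe set (from a probe set near the floor at baseline), MKI67 from 0.30 to -0.96 and -2.09, and MCL1 from 0.06 to -1.06 with every probe set, since other probe sets then set the value. Gene length and its matched lists were not run. Signal over background limits genes near the floor, with 30.8% to 35.7% of probe sets under an intensity of 16.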

Other observations

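Genes of the Integrator complex, which processes small nuclear RNAs and ends RNA polymerase II transcription near promoters, were not a list fixed in advance. They came from a scan, chosen after seeing the data, of 229 groups of at least 8 genes whose symbols open with the same letters, in which 3 were called. Of 11 genes named INTS, 7 fell and 0 rose, with a median log2 change of -1.10 as deposited, -0.67 after quantile normalization and -0.65 after median centring (camera, Benjamini-Hochberg adjusted p = 0.0132, 0.0499 and 0.0181). The call was lost with an estimated correlation (adjusted p = 0.996 as deposited and 0.924 on quantile-normalized values). The scanned groups were not set beside random lists of like brightness, so part of the INTS median can come from brightness. INTS6 had a log2 change of -2.83 with a standard error of 0.24, INTS7 of -2.11 with a standard error of 0.20 and INTS5 of -2.10 with a standard error of 0.22.

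Both other calls overlapped lists fixed in advance and ended in the smaller groups left without that overlap. Of 16 symbols that open with KLF, most of them Krüppel-like transcription factors, 6 rose and 1 fell, with a median of 0.48 (camera, Benjamini-Hochberg adjusted p = 0.0132; 0.068 after median centring; adjusted p = 0.996 with an estimated correlation). KLF9-DT (-0.03) and KLF3-AS1 (0.49) are non-coding transcripts, and 5 others belong to the immediate early list. Of the remaining 9 genes 4 rose and 0 fell, with a median of 0.83 and no call (camera, Benjamini-Hochberg adjusted p = 0.0824). These were KLF13, dim at baseline, KLF11 (1.75), KLF9 (1.11) and KLF3 (0.83). The third group, 50 genes whose symbols open with H and no further letter, had 2 rises, 2 falls (H2AX, -1.28, and H6PD, -0.93, not a histone gene) and a median of 0.22 (camera, Benjamini-Hochberg adjusted p = 0.0362; adjusted p = 0.996 with an estimated correlation). Its call was lost after quantile normalization (adjusted p = 0.13), after median centring (0.0951) and without the 18 genes of the histone list (0.16). The 32 genes left without that list had a median of 0.23, no smaller than that of the whole group.

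The change varied with brightness. In 10 groups of genes ordered by mean signal, the median log2 change was -0.13 in the dimmest group, -0.59 in the sixth and 0.09 in the brightest, and 412 genes fell in the sixth against 49 in the brightest. Each list was therefore set beside 10000 random lists of genes nearest in mean signal, after seeing the data, as a description in which genes are not independent replicates. Medians of homologous recombination (percentile 0.01), damage signalling (0.11) and G2/M genes (0), and of the uncalled G1/S (0.98) and mesenchymal and basal lists (1.72), lay below the middle 95% of random lists and those of immediate early factors (100) and histones (99.55) above, while those of Fanconi (11.7), excision and mismatch repair (5.22), ribosomal protein (32.3) and oxidative phosphorylation genes (79.2) lay within the range. Among the 3151 probe sets without a single gene, 115 rose and 312 fell.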
